A study of Caenorhabditis elegans with 2 samples.

How the data were processed

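The samples were 2 whole-animal ChIP-seq libraries of young adult C. elegans hermaphrodites carrying GFP-tagged ZTF-18, precipitated with an antibody to GFP, per the labels' protocols. The authors deposited peak lists in narrowPeak format on both ce10 and ce11, and those lists are the starting point here. For each replicate there was a relaxed list of peaks and background made as input for the irreproducible discovery rate, a method that keeps peaks ranked alike in both replicates. A relaxed list from both replicates together and a thresholded list derived from the others were used as well. The peak caller, aligner, filters and threshold are not given in the sources used here. The control alignment named by the authors was not analysed here. The peak signal is the value the authors deposited for each peak, relative to that control, on a scale that is not stated. The −log10 q of each peak was also deposited by the authors, and it had a single value of 2.78 for every thresholded peak, so peaks were ranked by signal. The thresholded list on ce11 was identical to the 2465 strongest peaks of the pooled relaxed list, so its members follow pooled signal. In it, 145 entries repeated the interval of another with a different summit, and 1433 had a width of exactly 510 bp. Read depth is unknown from these files.

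Positions were compared with the WBcel235 assembly, the same build as ce11, with gene models of annotation release 115. Many C. elegans transcripts are trans-spliced, so an annotated 5′ end can lie downstream of where transcription starts. No ce10 annotation was used here, so gene-based results are on ce11 alone. A gene was bound when a thresholded summit lay from 1000 bp upstream to 200 bp downstream of its 5′ end, on chromosomes I to V and X. Mitochondrial peaks entered the peak counts, the replicate comparisons, and the coverage and matrix tests of the closing part, and no gene comparison.

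Gene classes were tested where the annotation held at least 50 genes. Replicate overlap, promoter share, feature classes and gene classes were compared with 1000 circular shifts of the peaks within chromosomes. The rank correlation used 100000 permutations. Shares of bound genes used two-sided Fisher's exact tests, with 0.5 added to each cell for odds ratios and their intervals. Words of 6 bases were compared between the summit, within 50 bp, and the flanks at 250 to 300 bp by exact McNemar tests. Benjamini-Hochberg adjustment covered 34 gene lists, 10 gene classes, 6 feature classes or every strand-collapsed word of 6 bases, with a threshold of 0.05. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only.

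Gene lists, tests and the rule for named genes were fixed before the data were examined. The named genes are the nearest bound gene of the 15 strongest peaks with a bound gene and a top peak in each replicate, the tagged gene, the 4 strongest bound members of each list bound more often, and 2 of each list bound less often. A gene that this rule takes is not reported here. The gene hex-3 was named in addition because it shares a named peak. The ranges of signal rank, the 150 bp distance to tRNA genes and the aligned sequence were chosen after seeing the data. For the aligned sequence, the starting word, all 30 positions and the score threshold, the 99th percentile of flank scores, were taken from chromosomes I, III and V. An earlier version had 20 positions picked by eye and a threshold taken from chromosomes II, IV and X, and its result is given with the alternatives. The direction of a gene list under an alternative was first read from the odds ratio with 0.5 added. After those values were seen it was read from the bound shares instead, because the added 0.5 moves the odds ratio of a short list across 1. The rule that leaves a reproducibility test open when overlap is at its ceiling was also set after its value was seen.

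Alternatives covered a stricter list, each replicate alone, other promoter windows, other gene assignments, another background, other overlap rules and ce10. The tests were tried on simulated data. The gene list test found 10 of 10 raised lists and called 1 of 22 unraised ones among 19973 genes. Binding was simulated for each gene independently and no list was lowered. These counts therefore do not cover neighbouring genes that share a summit, or lists bound less often. The word test ranked the planted word first and called 1 of 1974 words unrelated to it. The simulated summits and flanks had the same base content, unlike the real ones, so this count does not cover calls due to base content. The shift test called 40 of 40 sets with a promoter preference and 2 of 40 without. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.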

Results

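The data describe where ZTF-18, a zinc finger protein of the nematode Caenorhabditis elegans, was found on DNA in young adult hermaphrodites. The worms carried a ZTF-18 transgene with a GFP tag, and chromatin was precipitated with an antibody to GFP, 64 hours after synchronization. There was 1 group with 2 samples, which the labels call biological replicates, so the design holds no treatment or control group to compare. The question was which sites and genes the tagged protein occupied, and how far both replicates gave the same sites. The deposited list of peaks that passed the reproducibility threshold held 2465 peaks on the ce11 assembly, with a median width of 510 bp and signals from 93.6 to 11118. Of these, 2449 lay on the nuclear chromosomes and 16 on mitochondrial DNA. Chromosome III carried 34.3 peaks per Mb (95% Poisson interval 31.3 to 37.6), and chromosome V carried 18.7 per Mb (16.9 to 20.7). The signal is the authors' own value for each peak, is used only to rank and describe peaks, and has no error of its own in the pooled list. Read depth is unknown from these files.

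Both replicates placed their strongest signal at the same genes. The peak of highest signal lay upstream of K12H4.5 (chromosome III, 8043539 to 8044480), and it ranked 1 of 26104 peaks in replicate 1 and 1 of 27612 in replicate 2. The peak next in rank lay between wip-1, a gene for a WASP-interacting protein, and larp-1, a gene for a La-related RNA-binding protein (III, 5017858 to 5018704), and ranked 2 in each replicate. Next came the peak at ntl-11, which encodes a CCR4-NOT complex subunit (IV, 15470979 to 15473063), at rank 4 in replicate 1 and 3 in replicate 2. Other peaks among the 15 strongest with a bound gene lay at hrpu-1, R06C1.4, ddp-1, cpg-1 (an eggshell proteoglycan gene), pcn-1, knl-3, eelo-2, rpl-24.2, fbxb-85, dnj-9 and eif-3.C. All 15 ranked 17 or higher in each replicate. Of the 2465 thresholded peaks, 1899 (77.0%) were overlapped by at least 1 bp by one of the 2465 strongest peaks of both replicates, against a mean of 2.19% after shifting the peaks along the chromosomes (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The share was 86.5% for replicate 1 alone and 88.2% for replicate 2 alone. The thresholded list holds the strongest peaks of the list pooled from both replicates, so overlap far above the shifts was built in. These shares and the p-value are therefore not independent evidence that the replicates agree. Across the 2455 peaks with an overlapping peak in both, signal in replicate 1 and replicate 2 had a Spearman rho of 0.817 (two-sided permutation p = 1e-05, the smallest possible). That correlation is across peaks, which are not independent replicates. Entries with repeated or overlapping intervals could take the same replicate peaks, so some pairs of values entered more than once. With summits matched within 100 bp, rho was 0.748 over 2302 peaks. In the lower-signal part of the list alone, a set chosen after seeing the data, rho was 0.167 over 1225 peaks. That part covers a narrow range of pooled signal, which both replicates feed, and this lowers rho by itself. The value therefore does not measure agreement of the weaker peaks. By overlap, 99.5% of nuclear peaks in the upper 1232 had a top peak of both replicates, against 54.6% in the lower-signal part. The share was 24.1% at ranks 2001 to 2465, where a peak can fall just outside the 2465 strongest of a replicate.

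**Figure D1:**
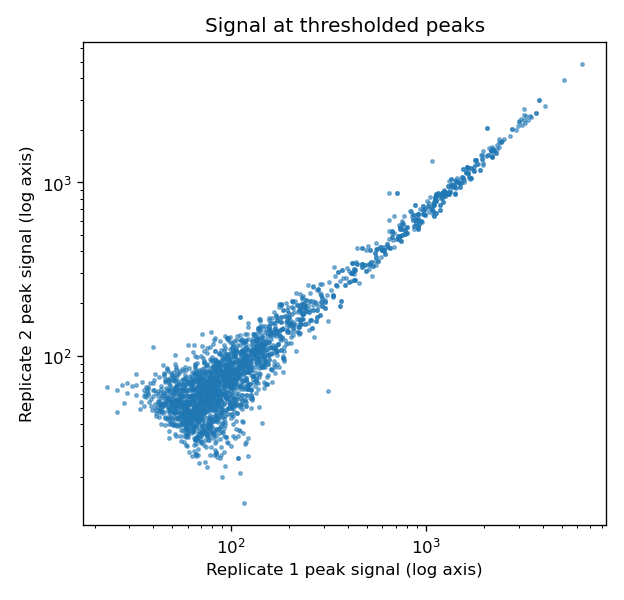
Signal of the highest overlapping peak in replicate 1 (x axis, log scale, authors' peak signal) against replicate 2 (y axis, log scale), 1 point for each of the 2455 thresholded peaks found in both. The Spearman rho over all points is 0.817.

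Peaks gathered immediately upstream of protein-coding genes. At pcn-1, the gene for the DNA replication clamp PCNA, the summit lay 272 bp upstream of the annotated 5′ end. At eif-3.C, a translation initiation factor subunit gene, it lay 234 bp upstream, and at dnj-9, a DnaJ chaperone gene, 222 bp upstream. The summit at hrpu-1, an hnRNP U family gene, was an exception among the 15 strongest gene-bound peaks, at 125 bp downstream of the 5′ end. Of the 2449 nuclear summits, 1368 (55.9%) fell in promoters, counted from 1000 bp upstream to 200 bp downstream of a protein-coding 5′ end, against 21.3% after shifting (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Regions within 1000 bp downstream of genes were also higher, at 7.35% against 5.62% (permutation p = 0.004, adjusted 0.0048), but among nuclear peaks of ranks 1 to 250 they were lower, at 2.53% against 5.49% (permutation adjusted p = 0.0456). Introns held 19.8% against 31.1%, other exons 4.33% against 21.2%, and other intergenic sequence 11.4% against 18.7%, each lower with permutation p = 0.002 and adjusted p = 0.003 over the 6 classes. The 5′ UTR or first exon class was lower at 1.35% against 2.1% (permutation p = 0.012, adjusted 0.012), and it did not pass with a promoter window reaching 2000 bp upstream (permutation adjusted p = 0.0579), among ranks 1 to 250 (0.244) or in the lower-signal part of the list (0.384). The promoter share fell over the strongest ranks. It was 97.9% (exact 95% interval 92.5 to 99.7) among nuclear peaks of ranks 1 to 100, 83.2% at ranks 101 to 250, 59.5% at ranks 251 to 500 and 49.6% (45.1 to 54.1) at ranks 501 to 1000, and in the 3 later ranges it was 49.8%, 53.4% and 52.9%. The lower ranges include summits near tRNA genes, of which 19.9% over all ranks fell in promoters. From rank 501 on, the promoter share of the 1594 nuclear summits not within 150 bp of a tRNA gene was 58.8%. The rank ranges were chosen after seeing the data.

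**Figure D2:**
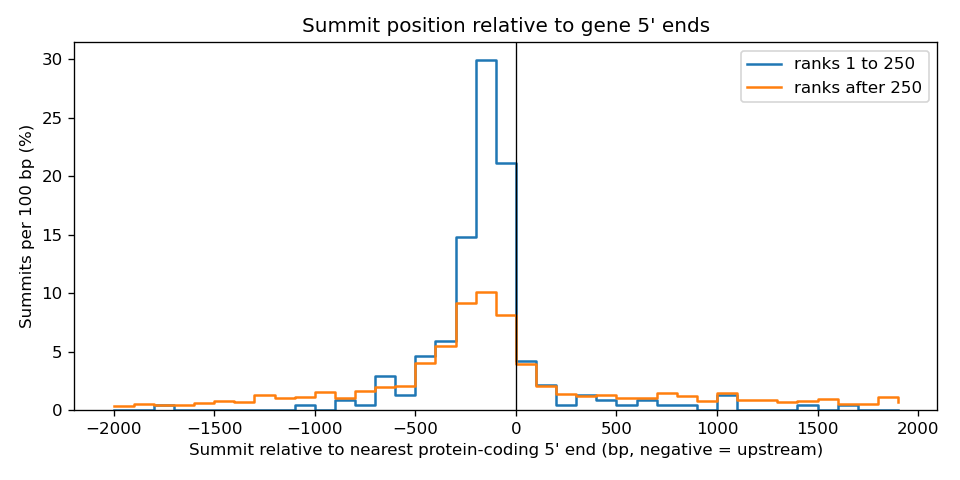
Percent of summits per 100 bp (y axis) by position relative to the nearest protein-coding 5′ end (x axis, bp, upstream negative), for nuclear peaks of ranks 1 to 250 (n = 237) and from 251 to the last (n = 2212). The medians are close, at -144 bp for the stronger peaks and -138.5 bp for the weaker, but the stronger are less spread, with 81.9% within 1000 bp upstream against 45.1% of the weaker.

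In all, 1634 of 19973 protein-coding genes (8.18%, exact 95% interval 7.80 to 8.57) were bound, a gene counting as bound when a thresholded summit lay in its promoter. Genes on the X chromosome were bound less often than autosomal genes. There were 151 bound genes among 2731 on X (5.53%) and 1483 among 17242 on autosomes (8.60%), an odds ratio of 0.624 (95% interval 0.525 to 0.741, two-sided Fisher's exact p = 1.58e-08). Among autosomal genes, those in the outer parts of the chromosomes, outside the central 50% by length, were bound less often than those in the centres. The shares were 6.46% of 7645 and 10.3% of 9597 genes, an odds ratio of 0.602 (0.538 to 0.673, Fisher's exact p = 1.74e-19). Both tests treat genes as units, and neighbouring genes that share a summit are not independent.

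The bound genes were rich in those that most cells need for protein synthesis, nuclear transport, respiration and division. Ribosomal protein genes were bound at 50 of 82 (60.98%, exact 95% interval 49.6 to 71.6) against 7.96% of other genes, an odds ratio of 17.95 (Fisher's exact adjusted p = 1.64e-32). The odds ratio was 9.07 when each summit counted only for its nearest 5′ end (30 genes bound), 7.37 against the genes bound in the relaxed pooled list and 4.84 in the upper 250 peaks, and the list passed each time (Fisher's exact adjusted p = 5.40e-15, 1.03e-15 and 0.0266). The strongest was rpl-24.2 with a pooled signal of 5394, followed by rpl-20 at 1792, rpl-25.2 at 1164 and rpl-35 at 1122. Among them rpl-24.2 alone had a match to the sequence aligned at the strongest peaks, described below. In the upper 250 peaks 5 of 82 ribosomal protein genes were bound. Nuclear pore and transport genes were bound at 20 of 36 (55.6%, odds ratio 14.1, Fisher's exact adjusted p = 3.73e-12), led by the nucleoporin gene npp-14, ran-5, the importin alpha gene ima-2, and npp-20. Oxidative phosphorylation genes were bound at 24 of 53 (45.3%, odds ratio 9.44, Fisher's exact adjusted p = 4.43e-12), led by mev-1, a succinate dehydrogenase subunit gene with signal 3541, then the cytochrome c1 gene cyc-1, nduf-11 and ucr-2.2. Translation factors were bound at 17 of 39, with eif-3.C, eef-1B.1, eif-3.D and eif-2Bdelta strongest (odds ratio 8.81, Fisher's exact adjusted p = 9.96e-09). Against the genes bound in the relaxed pooled list the odds ratios were lower, at 5.38 for nuclear pore, 3.81 for oxidative phosphorylation and 3.09 for translation factors, and each list passed.

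Cell division and chromatin genes were also bound more often. Of 71 cell cycle and DNA replication genes, 27 were bound (38.03%, odds ratio 7.03, Fisher's exact adjusted p = 2.08e-11). Their strongest members were pcn-1 at signal 5566, the kinetochore gene knl-3 at 5397, hcp-3, which encodes the centromeric histone CENP-A, at 3710, and the cullin gene cul-4 at 3425. Of 78 chromatin and synMuv regulators, 28 were bound (odds ratio 6.43, Fisher's exact adjusted p = 3.56e-11), led by set-4, trr-1, spr-2 and sir-2.1. Of 67 chaperone genes, 23 were bound (odds ratio 6.00, Fisher's exact adjusted p = 6.07e-09), with dnj-9, dnj-19 and the prefoldin genes pfd-3 and pfd-6 strongest. Of 64 cytoskeleton and polarity genes, 22 were bound (odds ratio 6.01, Fisher's exact adjusted p = 9.96e-09), led by the WAVE gene wve-1, the dynactin gene dnc-1, the beta-tubulin gene tbb-1 and erm-1. The peak of wve-1 is the one named above at R06C1.4, with its summit 628 bp upstream of wve-1 and 621 bp upstream of R06C1.4. Splicing factors were bound at 16 of 47 (odds ratio 5.93, Fisher's exact adjusted p = 1.51e-06). The SR protein genes rsp-1 and rsp-2 shared a single peak of signal 4527, and prp-40 and snrp-3 followed. Germline and maternal RNA regulators were bound at 20 of 75 (odds ratio 4.18, Fisher's exact adjusted p = 4.23e-06), with larp-1, ekl-1, the DEAD-box helicase gene cgh-1 and mut-2 strongest. Smaller groups passed as well. V-ATPase subunit genes were bound at 7 of 20, led by vha-13, vha-18, vha-1 and vha-8 (Fisher's exact adjusted p = 0.00154). Proteasome genes were bound at 9 of 33, led by rpn-2, rpn-9, pas-3 and pbs-7 (Fisher's exact adjusted p = 0.00204). Aminoacyl-tRNA synthetase genes were bound at 7 of 31, led by aars-1, ears-2, nars-1 and iars-1 (Fisher's exact adjusted p = 0.0189), and this call was lost without either replicate (adjusted p = 0.409 without replicate 1 and 0.130 without replicate 2). Against the genes bound in the relaxed pooled list the odds ratios were 3.04 for cell cycle, 2.895 for chromatin, 3.03 for chaperone, 2.80 for cytoskeleton and 2.27 for splicing genes, and these lists passed, the splicing factors with a Fisher's exact adjusted p of 0.0329. Against that background the germline, V-ATPase, proteasome and synthetase lists no longer passed by Fisher's exact test (adjusted p = 0.0579, 0.101, 0.519 and 0.601). In the upper 1232 peaks the V-ATPase, proteasome and synthetase lists did not pass by Fisher's exact test (adjusted p = 0.0924, 0.852 and 0.545), and with the nearest 5′ end only the V-ATPase and synthetase lists did not (0.0589 and 0.185). Among peaks found in both replicates the proteasome and synthetase lists did not pass by Fisher's exact test (adjusted p = 0.0832 and 0.531), nor did the synthetases with the 2000 bp window (0.104). In the upper 250 peaks the chromatin, cytoskeleton and proteasome lists did not pass by Fisher's exact test (adjusted p = 0.0849, 0.545 and 0.689), and 0 V-ATPase and 0 synthetase genes were bound.

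Large gene families with restricted expression were bound less often than other genes. Chemoreceptor genes were bound at 10 of 1309 (0.764%, exact 95% interval 0.367 to 1.40), an odds ratio of 0.0848 (Fisher's exact adjusted p = 7.82e-35). The strongest of them were srh-16 at signal 5028 and sri-5 at 4747. F-box and MATH/BATH genes were bound at 5 of 395 (Fisher's exact adjusted p = 6.07e-09), and the strongest, fbxb-85, shared its peak with hex-3, while fbxa-83 followed at signal 262.6. Innate immune effectors were bound at 7 of 356 (adjusted p = 2.09e-06 by Fisher's exact test), including clec-126 and spp-26. Cuticle collagens were bound at 3 of 175 (Fisher's exact adjusted p = 0.00106), including col-185 and col-63. Nuclear hormone receptors were bound at 8 of 274 (Fisher's exact adjusted p = 0.00116). Their strongest member, nhr-47, shared its peak with the chaperone gene dnj-19, and nhr-142 came next. The summit of the shared peak lay 7 bp upstream of nhr-47 and 389 bp upstream of dnj-19. Xenobiotic metabolism genes were bound at 6 of 202, including cyp-43A1 and gst-27 (Fisher's exact adjusted p = 0.00779), and neuropeptides and insulins at 3 of 142, including flp-23 and ins-39 (Fisher's exact adjusted p = 0.00885). Of the 34 lists, 13 were bound more often, 7 less often and 14 passed in neither direction. Sperm genes (2 of 91), histones (12 of 81), meiosis and repair genes (11 of 71), neuronal genes (1 of 70) and homeobox genes (6 of 100) were among those that did not pass. Under some alternatives lists of these 14 passed. With every transcript 5′ end meiosis genes were bound more often (odds ratio 2.198) and neuronal genes less often (0.224, Fisher's exact adjusted p = 0.0482 for both), and against the relaxed background muscle genes less often (0.179, Fisher's exact adjusted p = 0.0250). In the upper 1232 peaks the collagen, neuropeptide and hormone receptor lists were no longer past the threshold by Fisher's exact test (adjusted p = 0.0733, 0.0729 and 0.0912). Against the genes bound in the relaxed pooled list collagens and neuropeptides did not pass by Fisher's exact test (adjusted p = 0.0647 and 0.101), and the odds ratio rose from 0.0848 to 0.357 for chemoreceptors, from 0.155 to 0.283 for F-box genes and from 0.237 to 0.404 for immune effectors. With the nearest 5′ end only neuropeptides and xenobiotic genes did not pass by Fisher's exact test (adjusted p = 0.0905 and 0.0520), and neither did in the lower-signal part (0.148 and 0.171). In the upper 250 peaks chemoreceptors and immune effectors alone of these 7 lists passed, and F-box genes did not by Fisher's exact test (adjusted p = 0.0947). The peaks at clec-126, spp-26, col-185, cyp-43A1 and flp-23 lay within 150 bp of a tRNA gene.

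**Figure D3:**
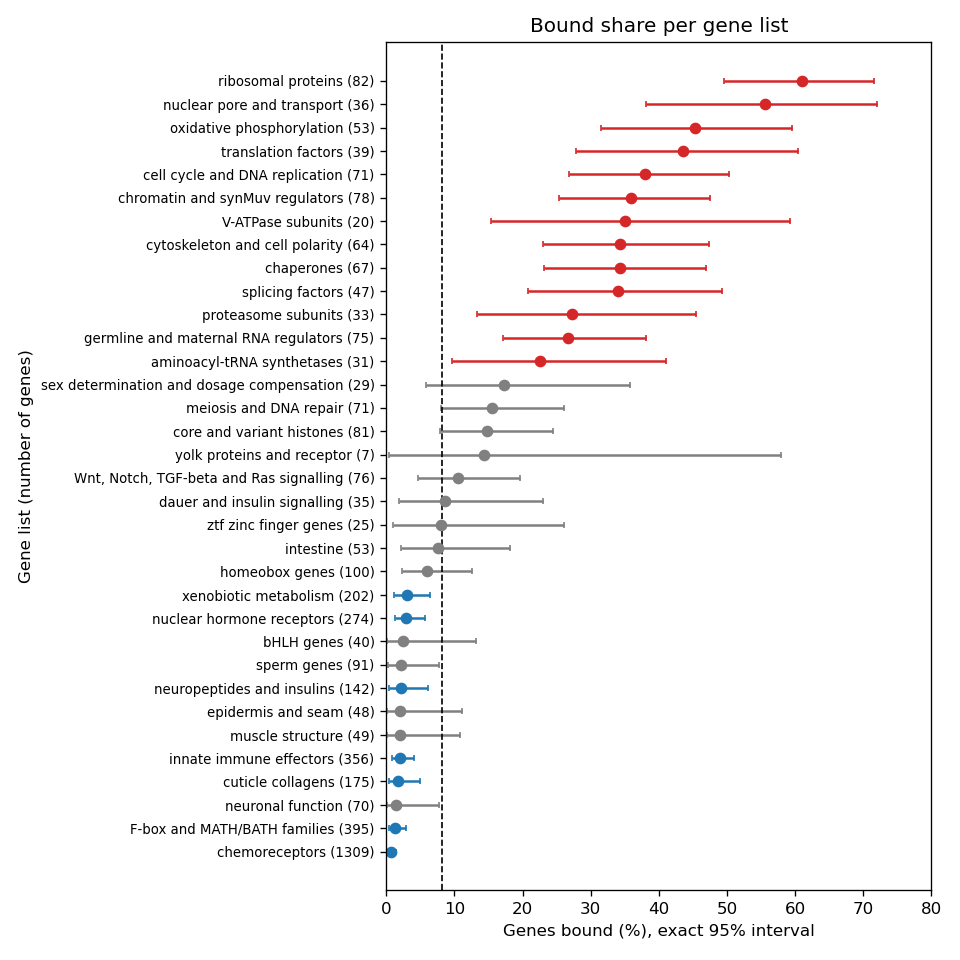
Percent of genes bound (x axis) in each of the 34 gene lists (y axis, number of genes in brackets), with exact 95% intervals as bars. Red points are lists bound more often than other genes, blue points less often, grey points did not pass, and the dashed line marks all protein-coding genes (8.18%). Ribosomal protein genes lie highest at 60.98% and chemoreceptors lowest at 0.764%.

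Transfer RNA genes had the highest bound share of the 10 annotated gene classes with at least 50 genes. With the same window, 444 of 612 tRNA genes (72.5%) were bound against 2.58% after shifting, a ratio of 28.1 (permutation p = 0.002, the smallest possible, adjusted 0.00285 over 10 classes). Small nucleolar RNA genes were bound at 122 of 346 (35.3%), as were 32 small nuclear RNA genes (24.8%) and 39 of 261 microRNA genes (14.9%), each with permutation p = 0.002 and adjusted p = 0.00285. In the upper 250 peaks the tRNA (1 of 612), snRNA (1 gene) and microRNA (0 of 261) classes did not pass (permutation p = 1, 0.603 and 1), while snoRNA genes did, at 6 of 346 (permutation adjusted p = 0.01998). Genes for piRNAs were bound less often than after shifting, at 0.814% against 2.35% (permutation p = 0.002, adjusted 0.00285). Pseudogenes, at 2.11% against 2.45%, did not pass (permutation p = 0.420, adjusted 0.466). A summit counted for every gene whose window held it, and these classes were not tested with the nearest 5′ end only. The share of a class can therefore include summits at neighbouring genes of other classes. The tRNA peaks were of middling signal. A summit lay within 150 bp of a tRNA gene for 0 of 94 nuclear peaks of ranks 1 to 100 (exact upper limit 3.85%), for 28.6% at ranks 501 to 1000 and for 8.17% at ranks 2001 to 2465. The 150 bp distance was chosen after seeing the data.

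The sequence under the summits differed from the flanks of the same peaks. The word GCGCCA lay within 50 bp of 380 of 2449 summits (15.5%) and in 69 flanks of equal length (2.82%), with an exact McNemar p of 2.38e-62 (adjusted 4.95e-59 over every word of 6 bases). In all, 728 words were more frequent and 449 less frequent at summits. Base content also differed, since G and C made up 46.5% of the sequence at summits and 36.1% in the flanks, so most of these words are not independent of it. Among the 237 nuclear peaks of ranks 1 to 250, GCGCCA was present at 67.5% of summits and 1.27% of flanks (exact p = 1.09e-47), the highest ratio of the 60 words of its base composition. Over all nuclear summits its ratio, 5.47, ranked 3 of those 60, and in the lower-signal part, at 2.90, it ranked 22. At ranks 501 to 1000 the leading word was CGAACC, at 15.8% against 1.40% (exact p = 2.76e-18, adjusted 5.74e-15), and from rank 1001 on it was CGTCTC, at 13.3% against 3.003% (exact p = 8.58e-26, adjusted 1.78e-22). At ranks 501 to 1000, 28.6% of nuclear summits lay within 150 bp of a tRNA gene. Among ranks 1 to 250 CGAACC was at 1.27% of summits and 2.11% of flanks. The words were not tested with the tRNA peaks left out, so CGAACC cannot be read as a separate binding sequence.

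A longer sequence was aligned around this word at the strongest peaks, an analysis added after seeing the data. In 151 copies from the 164 peaks of ranks 1 to 300 on chromosomes I, III and V, the most frequent bases over 30 positions read AGAACGAGAAATGCGCCAGCAACCTCTTTT, and the leading base exceeded 50% at 17 positions, of which 6 are the word itself and were fixed by the alignment. The ends were weak, with leading bases at 33.8% to 39.1% at positions 1 to 3 and at 27.8% to 43.7% at positions 22 to 30. Those end letters are therefore not a defined part of the sequence. The peaks of ranks 1 to 300 on chromosomes II, IV and X were then scored with the matrix of all 30 positions. Of those 120 peaks, 94 (78.3%, exact 95% interval 69.9 to 85.3) had a match within 75 bp of the summit, and 2 (1.67%) had one in a flank (92 at the summit only and 0 in the flank only, exact p = 4.04e-28). The match lay a median of 13.5 bp from the summit. Chromosomes II, IV and X had been looked at before the rank limit and window were chosen, so they are not a fully independent set. On these chromosomes a match was present at 88.6% of the 35 peaks of ranks 1 to 100 (exact 95% interval 73.3 to 96.8), at 14.3% of those of ranks 251 to 500 and at 4.08% of the 245 of ranks 501 to 1000.

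**Figure D4:**
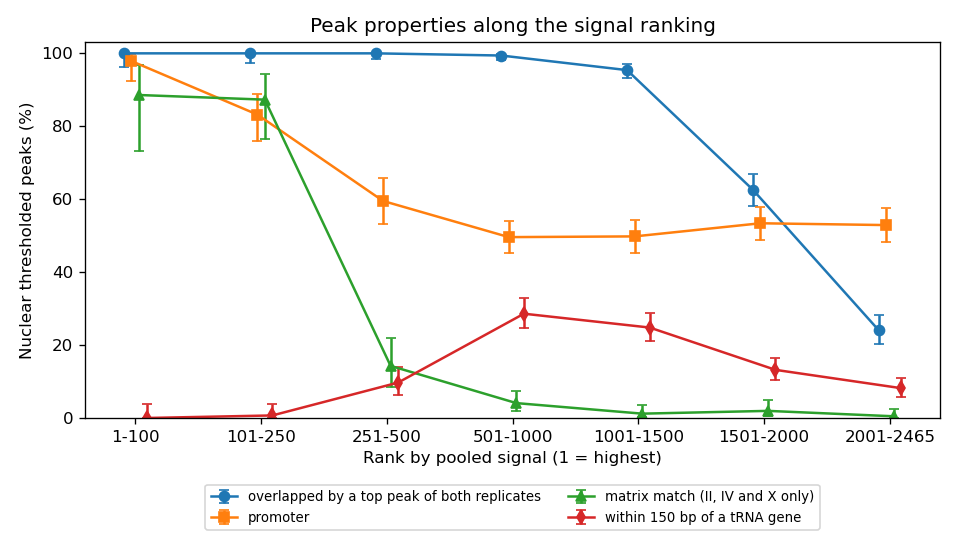
Percent of nuclear thresholded peaks (y axis) in 7 ranges of signal rank (x axis, 1 being the highest signal) that were overlapped by a top peak of both replicates, lay in a promoter, matched the aligned sequence (chromosomes II, IV and X only), or lay within 150 bp of a tRNA gene, with exact 95% intervals as bars. Matches fall from 88.6% to 4.08% between ranks 1 to 100 and 501 to 1000, while overlap by both replicates stays at 99.4% there and falls to 24.1% at ranks 2001 to 2465.

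The tagged gene itself was not bound. The gene ztf-18 (chromosome III, 891326 to 895712) had 0 thresholded peaks within 20 kb. The relaxed pooled list held 2 there, of which the stronger ranked 13956 of 30000, and the replicates held 2 and 1, with best ranks of 9612 and 23730. The ce10 list held 2453 thresholded peaks. Matched by rank with ce11, 2450 of 2453 had signals within 1% of each other, and 1537 of 2453 also had the same width. Both lists were ordered by signal before matching, and 57.9% of the ce10 and 58.1% of the ce11 peaks were 510 bp wide. Unlike peaks can therefore match too, so these counts do not show that both lists hold the same peaks.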

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

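All tests in this part were chosen after the result was seen. The 16 thresholded peaks on mitochondrial DNA lie outside every gene comparison, and they stand out because they are signal in data that the comparisons did not use. They fell in 10 intervals covering 8411 of 13794 bp (60.98%), against 1.07% of the nuclear genome, and the strongest ranked 5 of 2465. Binding to the sequence of the strongest nuclear peaks is argued against, since 0 of 16 mitochondrial summits had a match (exact upper limit 20.6%), while the lower limit for the strongest nuclear peaks was 69.9%. A candidate explanation is a larger amount of mitochondrial DNA in the precipitated sample than in the control. The 60.98% coverage is neither nearly complete nor confined to a small region, so this cannot be told apart from local signal without the control reads, which were not analysed here. No other biological explanation was tested.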

How the results depend on the processing

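The stricter list, the upper 1232 peaks, was fixed before the data were examined. The other subsets by rank or replicate overlap, and other windows for the feature classes, were chosen after seeing the data. Replicate overlap, rank correlation, promoter share and the X and arm comparisons kept their direction and side of the threshold under every alternative run, as did the other exon, intron and other intergenic classes. The downstream class reversed in the upper 250 peaks (ratio 0.461, permutation adjusted p = 0.0456), and the 5′ UTR or first exon class did not pass there (0.244), in the lower part (0.384) or with the 2000 bp window (0.0579). Promoter share ranged from 45.5% with a 500 bp window to 89.03% in the upper 250 peaks, and from 54.7% to 56.99% without 1 replicate. Without 1 replicate, bound genes numbered 1562 to 1567, and words more frequent at summits 666 to 673, with 13 lists bound more often and 8 less often in either case. The lists differed, since sex determination (odds ratio 4.68) and sperm genes (0.194) passed without replicate 1, and histones (2.54) and neuronal genes (0.083) without replicate 2. Calls were also gained in the lower part (meiosis, 3.41, and histones, 2.59), with every transcript (meiosis and neuronal), in peaks of both replicates (neuronal, 0.107) and against the relaxed background (muscle). Fewer peaks gave fewer bound genes (854 in the upper 1232 peaks, 292 in the upper 250, 859 in the lower part) and fewer words (128 in the upper 250, 441 in the lower part, 326 at ranks 501 to 1000). In the upper 250 peaks 8 lists were bound more often, 2 less often and 3 gene classes passed, with tRNA, snRNA, microRNA, lincRNA and other ncRNA classes losing their call (lincRNA also in the upper 1232, permutation adjusted p = 0.595, and without replicate 1, 0.0999), and in the upper 1232 peaks 4 lists were bound less often. Of the 20 lists past the threshold, 14 kept their call in the upper 1232 peaks, 14 against the relaxed background, 16 with the nearest gene only and 19 without each replicate. Direction was read from bound shares. For intestine (7.55% against 8.18%) and ztf genes (8.0% against 8.18%) the share was below other genes but the odds ratio, with 0.5 added, above 1. Of lists that had passed, V-ATPase and synthetases reversed, in the upper 250 peaks, where 0 genes were bound and the odds ratios of 1.64 and 1.07 come from the added 0.5. The other reversed lists had not passed, and none passed afterwards. In the upper 1232 peaks they were meiosis and repair (0.804), yolk (1.49, 0 bound), sex determination (1.18) and dauer genes (0.972). In the upper 250 they were histones (1.25), meiosis (1.43), ztf (4.13), signalling (1.34), yolk (4.48, 0 bound) and dauer genes (0.946, 0 bound). Against the relaxed background they were meiosis (0.973), homeobox (1.26), dauer (0.909) and signalling genes (0.955). In the lower part they were intestine (1.54) and homeobox (1.28), and among peaks in both replicates intestine (1.37) and dauer (0.655). They were intestine (1.33) and dauer (0.633) with the 500 bp window, intestine (1.12) and ztf (1.28) with the 2000 bp window, intestine (1.39) and ztf (1.63) with the nearest gene only, and dauer (1.12) with every transcript. Dauer genes reversed without replicate 1 (0.512) and without replicate 2 (0.876), and ztf genes without replicate 2 (1.25) but not without replicate 1 (0.721). Apart from the added 0.5, the cause was not tested. The match share was 85.0% in the earlier version of the aligned sequence and 78.3% in the one reported. No ce10 gene positions were used, so the tagged gene had no ce10 alternative.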

Other observations

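The test for weaker copies of the sequence was set before its result was seen, although matches at a stricter threshold had been seen, and the other tests in this part were chosen after. Peaks at tRNA genes were spread over the genome. A summit lay within 150 bp of 415 of 612 nuclear tRNA genes (67.8%), with 68.5% of the 276 on X and 67.3% of the 336 on autosomes, although protein-coding genes on X were bound less often than those on autosomes.

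The tRNA peaks may not share the mode of binding of the strongest peaks. Of 260 summits near tRNA genes on chromosomes II, IV and X, 0.385% had a match to the aligned sequence (exact 95% interval 0.00974 to 2.12). Of the 396 summits near tRNA genes, 87.4% were overlapped by a top peak of both replicates (83.7 to 90.5), so most were not signal in a single replicate. The list holds the strongest peaks by pooled signal, so high overlap was largely built in and is not independent evidence. Since 95.4% or more of nuclear peaks in each range down to rank 1500 were so overlapped, the 87.4% is not particular to tRNA genes. Signal at highly transcribed small RNA genes of any kind remains a candidate explanation, since 24.8% of snRNA genes were also bound, above the highest of the shifts at 9.30%. That share can include summits at neighbouring genes, and piRNA genes were bound less often than after shifting (0.814% against 2.35%). Whether signal at small RNA genes comes from the tagged protein cannot be settled here, since no precipitation from untagged worms was used. The same limit holds for the protein-coding gene lists bound more often.

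The strongest peaks and the rest may be of different kinds, since matches to the aligned sequence fell steeply with rank. Lower reproducibility cannot be told apart as a cause at ranks 501 to 1000. There 99.4% of peaks were overlapped by a top peak of both replicates and 100% in each higher range, so the measure was at its ceiling. Weaker copies of the same sequence can be judged only in part. The aligned copies all held GCGCCA, so a copy with a change in that word scored low. From rank 501 on, 23.4% of 916 summits on chromosomes II, IV and X scored above the 90th percentile of training flanks (exact 95% interval 20.7 to 26.2). That was under the 50% set in advance but above the 8.30% of their own flanks. From rank 1001 on, over all nuclear chromosomes, G and C made up 45.4% of the sequence at summits and 36.3% in the flanks used for words. Base content can therefore account for part of the higher share at summits. Scores above this limit were at a minority of these summits, and the test does not exclude weaker copies. Indirect binding and open chromatin were not tested.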
